A study of Mus musculus with 18 samples.

How the data were processed

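RNA abundance was measured by RNA sequencing in immortalized mouse hematopoietic progenitor lines. The lines came from bone marrow without lineage-marked cells, immortalized by retroviral MLL-AF9, a leukemia fusion gene, and cultured with interleukins and stem cell factor, per the labels' protocols. The cells carry a Cre recombinase, expressed from the Rosa locus, that 4-hydroxytamoxifen activates. The genotypes were no floxed Ddx41 allele (WT), a floxed allele beside a normal one (Het), and both alleles floxed (FF). Each genotype was treated for 48 h with 1 µM 4-hydroxytamoxifen (4OHT) or with ethanol (EtOH), and each of the 6 groups has 3 libraries, lettered A to C, which makes 18. Total RNA was extracted, and the labels do not name the library kit or its selection step. The labels say neither how many lines stand behind a genotype nor that the letters are separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical, and genotype and line cannot be told apart.

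The deposited table holds whole-number read counts per gene symbol, not normalized, for all 18 libraries. Per the submitters' processing notes, CASAVA 1.4, FastQC 0.11.7, HISAT2 2.0.5, Subread and featureCounts 1.5.2 were used with the mm10 build. The strand setting, the gene annotation and the handling of reads that match several places are not given in the sources used here. Reads of a small RNA inside an intron of its host gene, of overlapping genes and of near-identical copies may therefore be assigned in ways that cannot be recovered from counts. The table has 24062 symbols and no blank or summary entry. In GENCODE M21 (GRCm38, the assembly of mm10), 22708 symbols matched exactly 1 gene, 42 matched several and 1312 matched none. Coordinates come from that annotation.

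Library totals ranged from 24730213 to 49277884 counts, so that 1 count corresponds to between 0.0203 and 0.0404 CPM (counts scaled to a common library total). No pair among the 153 library pairs had identical counts, and the smallest chi-square per gene over these pairs was 9.53, far above sampling noise, so each library was counted once. Intervals and floors cover counting error only. A group with no count for a gene was given a floor of 3 counts over the group. Ratios against 1 to 3 counts carry an exact 95% counting interval.

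Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, in a single fit to all 18 libraries with 1 mean per group, TMM normalization, filterByExpr (minimum count 10) and the robust quasi-likelihood F test. The filter left 12859 genes. Adjusted p-values are Benjamini-Hochberg values and the threshold is 0.05. Fold changes are log2 values with a standard error derived from the F statistic, and means are TMM-normalized CPM ± SD with n = 3. The comparisons are 4OHT against ethanol in each line, the 3 differences between those responses (interactions), and FF and Het against WT in ethanol. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, for the 29 lists that have at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Principal components used log2 CPM with a prior count of 2.

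Before the data were examined, 32 gene lists, the alternatives and the rule for naming genes were fixed. After Ddx41, the rule names the 10 largest rises and 10 largest falls of the FF response, and 5 of each in every other comparison, among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. For interactions the overlap condition is on the arm named first. Uncharacterised gene models were passed over. From each list it takes up to 4 members past the threshold in FF with the smallest adjusted p and at least 1 CPM, or 2 of the most abundant where none passes. The values of some genes that the rule takes are not reported here, while counts over all genes and over lists include them. Gbp11 and Gm7694 were named after their values were seen, because they are the only 2 calls of their comparison.

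Letters are shared between groups, so it was checked whether libraries of the same letter deviate together from their group means. In Het the correlations were 0.48, 0.70 and 0.40 for A, B and C, so the letters pair the Het libraries and the value with a replicate block is given beside the Het result.

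Alternatives were DESeq2 size factors, scaling by library size, no count filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit to the compared groups alone, a replicate block, a 2-fold limit, an adjusted p of 0.01, and each library left out in turn. Added after the data had been seen were fits without 2 libraries that lie with the other line (the libraries labelled FF_EtOH C and WT_4OHT C), without those and Het_4OHT A, without those and WT_EtOH C, whose Tgm2 level went against its label, and with a replicate block within each line. No library was moved to another group. The code was tested on simulated counts with real means, library sizes and dispersions, with 198 genes changed in Het, 197 in WT and 242 in FF, where all 42 spliceosome genes were raised together as well. For the FF response, edgeR on 12680 simulated genes recovered 16.4% of 1.5-fold, 58.2% of 2-fold and 78.8% of 4-fold changes, and 8.06% of its calls were false. For Het the shares recovered were 10.6%, 58.2% and 78.5%, and for WT 10.6%, 48.5% and 90.8%. The simulated libraries all followed their group means, with no library out of place and no shared deviation by letter. These shares therefore do not give the power of the fits to the real libraries, where Thbs1 was at -5.45 in Het without a call.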

Results

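The data comprise 18 RNA-seq libraries of MLL-AF9 immortalized mouse progenitor lines, 3 in each of 6 groups, with 24730213 (FF_4OHT C) to 49277884 (Het_EtOH A) counts per library. The design addresses how progenitors respond to loss of Ddx41, a DEAD-box RNA helicase, at 48 h after Cre induction, a time chosen per the series' design text to precede the death of cells without either allele.

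Ddx41 itself was examined first. The gene lies on chromosome 13 (GRCm38, 55530410 to 55536658, minus strand, protein coding). In FF cells it fell from 89.16 ± 20.02 CPM in ethanol to 16.3 ± 1.54 CPM in 4OHT (SD, n = 3), which is 18.2% of the ethanol mean (log2 fold change -2.45 ± 0.17 SE, edgeR adjusted p = 8.09e-07). In Het cells the 4OHT mean was 65.4% of the ethanol mean (log2 -0.61 ± 0.16). The highest Het 4OHT library, at 58.4 CPM, lay below the lowest Het ethanol library, at 68.0 CPM. The edgeR adjusted p of 0.86 is taken over all 12859 tested genes, so it does not show that Ddx41 was unchanged in Het. In WT cells the 4OHT mean was 102% of the ethanol mean (log2 0.03 ± 0.16, edgeR adjusted p = 1). The FF response differed from WT (log2 difference -2.49, edgeR adjusted p = 5.65e-05) and from Het (-1.84, adjusted p = 0.00214). Gene counts do not resolve exons, so they do not give the share of alleles that recombined.

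**Figure D1:**
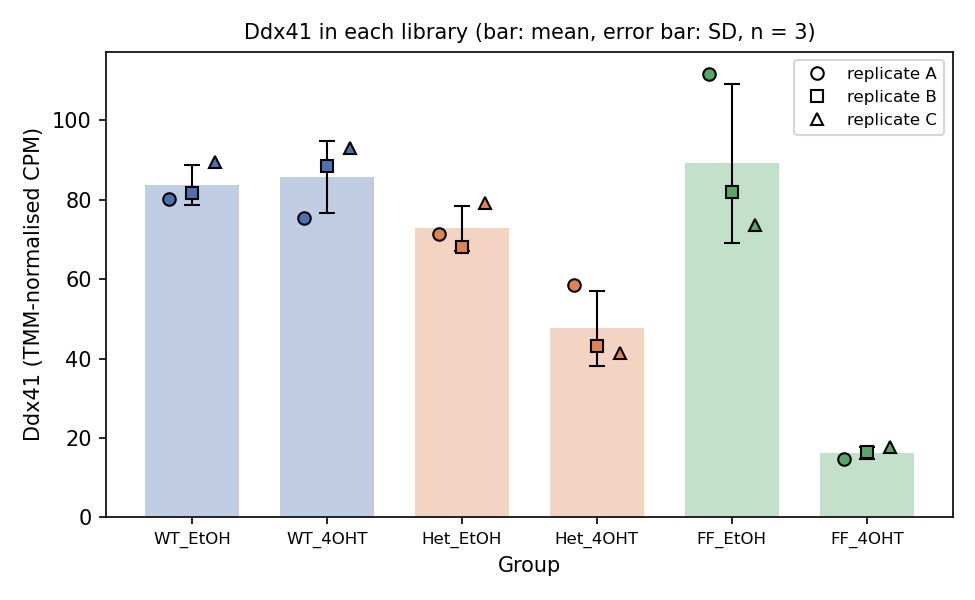
Ddx41 in TMM-normalized CPM (vertical axis, from 0) for the 6 groups (horizontal axis). Points are libraries A to C, bars are means and error bars SD (n = 3). The FF 4OHT libraries have a mean of 16.3 CPM against 89.2 CPM in FF ethanol.

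Libraries separated first by line. The leading principal component held 53.5% of the variance and parted Het from the other lines, and the next held 16.5%. The libraries FF_EtOH C and WT_4OHT C lay with the other line. On an axis from the WT libraries (0) to the FF libraries (1), defined without these 2, the library labelled FF_EtOH C lay at 0.029 and the library labelled WT_4OHT C at 0.867. Eif2s3y, a Y-linked translation factor gene, was at 86.3 CPM in the library labelled FF_EtOH C and had 0 counts in the other 5 FF libraries. It had 0 counts in the library labelled WT_4OHT C and 66.4 to 101 CPM in the other 5 WT libraries. Ddx41 was at 73.7 CPM in the library labelled FF_EtOH C and 93.0 CPM in the library labelled WT_4OHT C, within the range of groups without deletion. At 27 genes whose treatment difference had 1 sign in all 3 lines, found without these 2 libraries, WT_EtOH C and Tgm2, the library labelled WT_EtOH C lay on the side of WT_4OHT A and B at 24 and the library labelled FF_EtOH C at 1. All were kept under their labels, and values without the 2 libraries, or without these and WT_EtOH C, are given where they change a call. The library Het_4OHT A also stood apart, with a mean correlation of 0.959 to its group. Rn45s, the ribosomal RNA precursor, reached 14841 CPM there, and 18227 and 40003 CPM in FF_4OHT B and C, against 6003 CPM in FF_4OHT A.

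**Figure D2:**
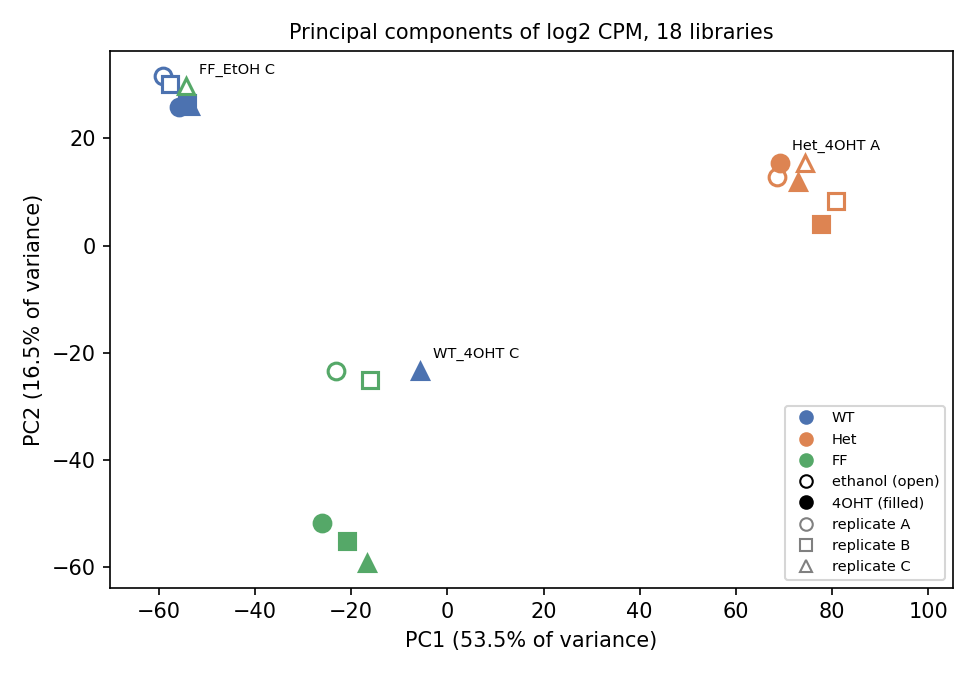
Scores of the 18 libraries on the leading principal components of log2 CPM, with 53.5% (horizontal axis) and 16.5% (vertical axis) of the variance. Colours are lines, shapes are letters A to C, open symbols ethanol and filled symbols 4OHT. The libraries labelled FF_EtOH C and WT_4OHT C each sit among libraries of the other line.

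In FF cells given 4OHT, members of the snoRNA, p53, monocyte, interferon and inflammatory lists rose, and members of the mitosis, replication, repair, amino acid and sterol lists fell. Camera called 16 of 29 lists with the preset correlation and 1, G2/M and mitosis, with an estimated correlation (adjusted p = 0.00876). Other splits of the FF libraries gave 10 to 16 lists with the preset correlation, and 0 genes. The number of preset list calls therefore does not set the treatment apart from other groupings. Of 12859 genes, 663 rose and 1066 fell in edgeR at an adjusted p of 0.05. Of these, 342 rose and 182 fell by at least 2-fold. Without the libraries labelled FF_EtOH C and WT_4OHT C there were 578 higher and 981 lower, of which 444 and 821 were called in both fits. The count was 961 without FF_4OHT B and 700 without FF_4OHT C.

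The largest rises included the snoRNAs Snora7a (log2 3.01 ± 0.44) and Snora70 (2.67 ± 0.38), the C-type lectin Clec4n (2.98 ± 0.40), the scavenger receptor Msr1 (2.85 ± 0.64) and the protease inhibitor Spint1 (2.71 ± 0.54). Phlda3, a p53-induced inhibitor of AKT, rose from 4.84 ± 1.65 to 29.9 ± 3.68 CPM (SD, n = 3). The neutrophil collagenase Mmp8 (2.63), Saa3 (2.61), Fblim1 (2.49) and the proteoglycan Vcan (2.48) were the other rises named. Among falls, Tgm2, a transglutaminase, went from 372 ± 86.2 to 23.9 ± 3.64 CPM. Its log2 value was -3.96 in both FF and Het, and in Het it did not pass over all libraries (edgeR adjusted p = 1) or without the 2 libraries (0.0551). It passed in Het (-3.99, edgeR adjusted p = 0.00173) without these and WT_EtOH C, a library left out for its Tgm2 level. In WT it was at 25.4 CPM in the library labelled WT_EtOH C and 480 CPM in the library labelled WT_4OHT C, against 220 and 227 CPM in WT_EtOH A and B and 18.01 and 17.28 CPM in WT_4OHT A and B. Other falls were Plekhh2 (-2.61), Far2 (-2.37), the desaturase Scd1 (-2.21), N4bp3 (-2.17), the branched-chain aminotransferase Bcat1 (-2.15) and myeloperoxidase, Mpo (-2.02). Phlda3, N4bp3 and Scd1 are among the 27 genes found for a treatment difference of 1 sign in all 3 lines. In WT A and B, Phlda3 went from 4.09 and 4.21 CPM in ethanol to 9.38 and 10.4 CPM in 4OHT. N4bp3 went from 6.68 and 7.07 to 1.91 and 1.94 CPM, and Scd1 from 41.8 and 52.9 to 25 and 32.5 CPM. The libraries labelled WT_EtOH C and WT_4OHT C went the other way. Cth, an enzyme of cysteine synthesis, fell by 2.92, and by 1.59 without the library labelled FF_EtOH C. Skida1 fell by 7.99, with 828 counts in FF ethanol against 3 in 4OHT, a ratio of 274 (95% counting interval 93.4 to 1330). That fold rested on the library labelled FF_EtOH C: without the 2 libraries it was -0.95 (edgeR adjusted p = 0.604). Mansc1 (-3.30), Saa3 and Vcan also lost their calls there (edgeR adjusted p = 0.0729, 0.105 and 0.0518). Mansc1 was at -1.22 without the library labelled FF_EtOH C alone. Leaving out single libraries ended the calls of Saa3 for each of the 6 FF libraries (edgeR adjusted p 0.0511 to 0.105) and of Vcan for FF_EtOH A and C (0.0573 and 0.0512). It ended those of Skida1 and Mansc1 for FF_EtOH C and for each 4OHT library (0.108 to 0.877 and 0.0758 to 0.4). Tgm2 and N4bp3 lost theirs for FF_EtOH A and each 4OHT library (0.0555 to 0.104 and 0.0611 to 0.0957), and Far2 and Mpo for FF_EtOH A and C and FF_4OHT B and C (0.0676 to 0.142 and 0.0796 to 0.161).

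Cell cycle genes fell together. Of 37 G2/M and mitosis genes, 29 fell and none rose (36 adjusted over the list alone), with a median of -0.63. Examples were the cyclin Ccna2 (-0.85 ± 0.12) and the kinesin Kif20a (-0.84 ± 0.09), with Ckap2l at -0.72 and Dlgap5 at -0.59. This was the only list past the threshold with an estimated correlation (camera adjusted p = 8.62e-22 preset, 0.00876 estimated). Camera gave it as down in WT too (median -0.09, adjusted p = 0.00219 preset, 0.732 with an estimated correlation). Of 38 S phase genes, 14 fell (25 adjusted over the list alone), including the clamp loader subunit Rfc5 (-0.94), the polymerase Pold1 (-0.78), the helicase subunit Mcm7 (-0.73) and Clspn (-0.66). Of 30 DNA repair genes, 14 fell (24 adjusted over the list alone), including Fancb (-0.99), Rad54l (-0.75) and Fanca (-0.72). The camera calls of both were lost with an estimated correlation (adjusted p = 0.0991 for each).

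Of 35 p53 targets, 16 rose and none fell (19 adjusted over the list alone, median 0.66), including Zmat3 (1.52), Psrc1 (1.10) and the death receptor Tnfrsf10b (1.04). The call was lost with an estimated correlation (adjusted p = 0.0806). No p53 target passed in Het or WT, but camera gave the list as up in Het (median 0.09, adjusted p = 0.00777 preset, 0.845 with an estimated correlation). It did so in WT without the 2 libraries (median 0.11, 9.41e-07 preset, 0.233 with an estimated correlation), though not with them (0.521). Without these and WT_EtOH C the WT median was 0.26, with 28 members above 0 and 7 below. Camera adjusted p was then 3.55e-07 preset and 0.387 with an estimated correlation, and the FF median in that fit was 0.67. The FF response of the list differed from that of WT and Het with the preset correlation (camera adjusted p = 1.67e-09 and 3.04e-06), and these calls were lost with an estimated correlation (adjusted p = 0.0955 and 0.114). Against WT, without the 2 libraries and WT_EtOH C, camera adjusted p was 3.46e-05 preset and 0.303 with an estimated correlation. Of 25 BCL2 family and caspase genes, Casp8 (0.61) and Mcl1 (0.33) rose and 3 fell, including Bid (-0.55) (camera adjusted p = 0.967). Mcl1 did not pass without the 2 libraries (edgeR adjusted p = 0.102), nor without any single FF library but FF_EtOH A (0.0521 to 0.134).

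Of 71 snoRNAs, 27 rose and none fell (36 adjusted over the list alone, median 1.41). Snora16a (2.87) and Snord88c (2.61) were the others named. Of 17 snoRNA host transcripts, 6 rose (7 higher and 2 lower adjusted over the list alone), including Snhg1, from 76.0 ± 13.6 to 251 ± 19.2 CPM, Snhg12 (1.398), Snhg3 (1.06) and Gas5 (0.98). With an estimated correlation the adjusted p was 0.0737 for snoRNAs and 0.262 for hosts. That of snoRNAs was 0.0366 without the 2 libraries and WT_EtOH C. Rn45s was highest in FF_4OHT B and C, beside this rise. Among 51 ribosome biogenesis genes 5 fell, including the RNA polymerase I subunit Polr1a (-0.82), Nat10 (-0.59), Dkc1 (-0.52) and Bop1 (-0.42) (camera adjusted p = 0.574 with an estimated correlation). Dkc1 did not pass without FF_EtOH A or FF_4OHT C (edgeR adjusted p = 0.0502 and 0.12), nor Bop1 without FF_EtOH B or any 4OHT library (0.0548 to 0.07). No cytosolic ribosomal protein gene passed among 76 (median 0.23, adjusted p = 0.671 with an estimated correlation). Rplp0 was at 0.16 and Rpsa at 0.13. None passed among 77 mitochondrial ribosomal protein genes (median -0.10, camera adjusted p = 0.498), with Mrpl12 at -0.10 and Mrpl18 at -0.01, and without the 2 libraries 2 of them fell. Without these and Het_4OHT A, 15 cytosolic members rose and 6 mitochondrial members fell.

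Of 22 monocyte and macrophage genes, 10 rose and none fell (12 adjusted over the list alone, median 1.497). Lysozyme, Lyz2, rose from 229 ± 45.5 to 1175 ± 188 CPM (SD, n = 3), and Mpeg1 (2.03), Ctss (1.97) and the receptor Csf1r (1.57) rose as well. Of 31 interferon-stimulated genes, 15 rose (20 adjusted over the list alone, median 0.88), including Gbp2 (1.76), Oas2 (1.21), Irf9 (1.09) and Ddx58 (0.60). Without the 2 libraries 7 rose, and Ddx58 did not pass (edgeR adjusted p = 0.0574). Of 22 NF-kB and cytokine genes, 5 rose (9 adjusted over the list alone, median 1.22), including Ccl6 (2.20), Relb (1.71), the inhibitor Nfkbia (1.30) and Icam1 (0.68). With an estimated correlation the adjusted p was 0.0991, 0.0991 and 0.0824 for these lists. Camera with the preset correlation gave the NF-kB list as up in WT and Het too (medians 0.37 and 0.13, adjusted p = 0.00219 and 0.0484), the monocyte list in Het (0.41, 0.0484) and the interferon list in WT (0.14, 0.0473), and with an estimated correlation none of these (adjusted p 0.732 to 0.845). The monocyte list was not past the threshold in Het without Het_4OHT B (0.515). In WT it had an adjusted p of 0.276 over all libraries and 1.19e-06 without the 2 libraries (0.53 with an estimated correlation). The FF responses of the monocyte, interferon and NF-kB lists differed from WT by medians of 1.01, 0.59 and 0.44 (camera adjusted p = 3.37e-08, 2.43e-05 and 0.00145 preset, 0.195 each with an estimated correlation). For NF-kB the median difference was 0.27 without the 2 libraries (adjusted p = 0.0713). Without these and WT_EtOH C it was also 0.27 (camera adjusted p = 0.0472 preset, 0.532 with an estimated correlation). Against Het the adjusted p of the monocyte, interferon and NF-kB lists was 1.45e-06, 2.69e-07 and 0.000225 preset, and 0.199, 0.114 and 0.122 with an estimated correlation. Of 15 DNA and RNA sensing genes, Tlr7 (2.12) and Samhd1 (0.55) rose (camera adjusted p = 0.102). Without FF_4OHT C, Oas2, Samhd1 and Ddx58 did not pass (edgeR adjusted p = 0.071, 0.0668 and 0.0687), nor Ddx58 without FF_EtOH B or C (0.0591 and 0.0581).

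Of 29 ATF4 and amino acid genes, 12 fell and none rose (15 adjusted over the list alone, median -0.52). They included Shmt2 (-0.89), the asparagine synthetase Asns (-0.85), the serine synthesis enzyme Phgdh (-0.79) and Eprs (-0.53). Of 21 ER chaperone genes, 5 fell (7 adjusted over the list alone), including Sdf2l1 (-0.95), Herpud1 (-0.75), Hsp90b1 (-0.43) and Hspa5 (-0.39). Of 23 cholesterol synthesis genes, 9 fell (13 adjusted over the list alone, median -0.43), including Tm7sf2 (-1.10), Nsdhl (-1.04) and Dhcr7 (-0.71). The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.0991 for each). No cholesterol synthesis gene passed in WT or Het, but camera gave that list as down there too (medians -0.12 and -0.13, adjusted p = 0.00219 and 0.00336 preset, 0.732 and 0.845 with an estimated correlation). Without the 2 libraries all 23 were below 0 in WT (median -0.22, adjusted p = 8.22e-14 preset, 0.138 with an estimated correlation), and without these and Het_4OHT A all 23 were in Het (median -0.15, preset adjusted p = 7.01e-07). The FF response of the list differed from that of WT and Het with the preset correlation (adjusted p = 5e-05 and 5.94e-05), and these calls were lost with an estimated correlation (adjusted p = 0.258 and 0.185). Nsdhl and Tm7sf2 differed from WT (-0.88 and -1.25, edgeR adjusted p = 0.0112 and 0.028), but not without the 2 libraries (0.0541 and 0.0967). The ER chaperone list was also given as down in WT (median -0.06, adjusted p = 0.032 preset, 0.732 with an estimated correlation). Hspa5 did not pass without the 2 libraries (edgeR adjusted p = 0.1) or any single FF library but FF_EtOH A (0.0654 to 0.144), nor Hsp90b1 without FF_EtOH B, FF_4OHT B or FF_4OHT C (0.0606 to 0.128).

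Apart from the monocyte list, camera called no progenitor or lineage list. Of 26 MLL-AF9 and stem genes, Hoxa5 rose (0.84) and Bcat1, Myc (-0.61) and Myb (-0.33) fell. The median was -0.03 while camera gave the list as up (adjusted p = 0.967). Myb did not pass without the 2 libraries (edgeR adjusted p = 0.145) or any single FF library but FF_EtOH A (0.0636 to 0.243), nor Myc without any but FF_EtOH C (0.0547 to 0.157). Among 21 granule genes Mmp8 rose and Mpo fell (camera adjusted p = 0.699). No mast cell gene among 8 passed (Hdc -0.87, Mcpt8 0.05, list median 0.69, camera adjusted p = 0.515), and none of 3 erythroid (Car2 0.11, Klf1 -0.55) or 3 stromal genes (Pdgfrb -0.91, Lepr 0.10) did. The stromal median was 0.10 and its mean -0.11, and these lists of 3 were too short for camera. Pdgfrb fell without the 2 libraries and WT_EtOH C (-1.49, edgeR adjusted p = 0.0403). Vwf (1.86) rose among 6 platelet genes and Nkg7 (-0.96) and another fell among 6 lymphoid genes (camera adjusted p = 0.287 and 0.515). Vwf and Nkg7 did not pass without FF_EtOH A, FF_EtOH B, FF_4OHT B or FF_4OHT C (edgeR adjusted p 0.0519 to 0.079 and 0.0559 to 0.144).

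Of 42 spliceosome genes, Prpf3 (0.69) rose and Srsf6 (-0.97), U2af2 (-0.38), Eftud2 (-0.36) and another fell (camera adjusted p = 0.334). Of 34 other DEAD-box genes, 2 rose, Ddx58 and Ddx55 (0.55), and 3 fell, including Ddx59 (-0.80) and Ddx50 (-0.49). The DEAD-box median was -0.01 while camera gave the list as up (adjusted p = 0.699), and adjusted over the list alone 3 were higher and 4 lower. U2af2 did not pass without FF_EtOH A or FF_4OHT C (edgeR adjusted p = 0.052 and 0.0743), nor Eftud2 without FF_4OHT C (0.0841), Ddx50 without FF_EtOH C or FF_4OHT C (0.0561 and 0.104), Ddx59 without FF_EtOH A, FF_4OHT B or FF_4OHT C (0.0607 to 0.0761), and Ddx58 without FF_EtOH B, FF_EtOH C or FF_4OHT C (0.0581 to 0.0687).

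Of 34 replication-dependent histone genes Hist1h4i rose (1.06), with camera adjusted p = 0.558 with an estimated correlation, and not without FF_EtOH A (edgeR adjusted p = 0.0501). Of 16 NRF2 targets, Hmox1 (1.45), Fth1 (0.64) and Sqstm1 (0.55) rose (camera adjusted p = 0.0875). Fth1 and Sqstm1 did not pass without the 2 libraries (edgeR adjusted p = 0.128 and 0.0843). Ier5 (0.73) rose among 19 immediate early genes, and not without the 2 libraries (edgeR adjusted p = 0.0526). Pfkp (-0.70) fell among 22 glycolysis genes, none adjusted over the list alone (camera adjusted p = 0.574 with an estimated correlation). Leaving out single FF libraries ended the call of Pfkp each time (edgeR adjusted p 0.0703 to 0.136), of Hmox1 for FF_4OHT C and each ethanol library (0.0724 to 0.138), and of Fth1 for FF_EtOH B and C and FF_4OHT B and C (0.0521 to 0.144). It ended that of Sqstm1 for each but FF_4OHT B (0.0565 to 0.172) and of Ier5 for FF_EtOH B and C and FF_4OHT A and C (0.0656 to 0.0879). No heat shock gene passed among 12 (Hsp90ab1 -0.06, Hsp90aa1 -0.18, camera adjusted p = 0.0938). Immediate early genes had a camera adjusted p of 0.259. The table held no mitochondrially encoded gene.

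**Figure D3:**
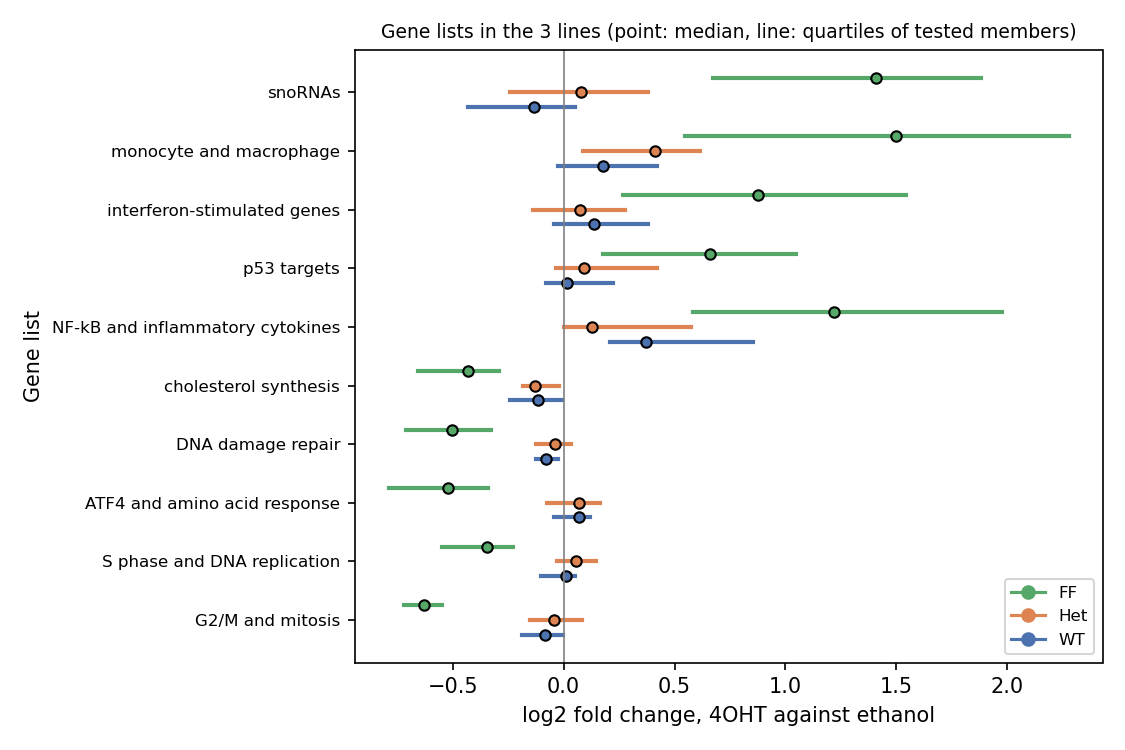
Log2 fold change of 4OHT against ethanol (horizontal axis) for tested members of 10 gene lists (vertical axis) in FF, Het and WT. Points are medians and lines quartiles. The snoRNA median was 1.41 in FF and the G2/M median -0.63.

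The Het response, which combines 4OHT and Cre induction with loss of a single allele, gave few calls. In edgeR 2 genes fell and none rose, the guanylate-binding protein gene Gbp11 (127 counts in ethanol and 1 in 4OHT, a ratio of 109 with a 95% counting interval of 19.1 to 4320) and Gm7694 (log2 -1.52 ± 0.21). The count at an unadjusted p of 0.05 was 246, and DESeq2 called 17. With the replicate block, a letter term shared by all lines, 0 genes passed, and 1 did with the block within each line. Gbp11 did not pass without any single Het library (edgeR adjusted p 0.0693 to 0.368), nor Gm7694 without Het_EtOH A, Het_EtOH B, Het_4OHT A or Het_4OHT C (0.0766 to 0.228), so 0 or 1 gene was left. In Het 12 genes fell without the 2 libraries and WT_EtOH C, including the matrix protein gene Thbs1 (-5.46). The Het libraries were the same as in the main fit, where Thbs1 was at -5.45 without a call. Few calls over all libraries therefore do not show that Het cells did not respond. In WT, where 4OHT meets no floxed allele, edgeR called 0 genes, with 275 at an unadjusted p of 0.05, 0 in limma voom and 4 in DESeq2. The 246 genes in Het and 275 in WT are less than 0.05 of the 12859 tested genes, the share that no response would give. These 2 counts are therefore no sign of a weaker response. The WT count of 0 rests on a 4OHT group that holds the library labelled WT_4OHT C, which lay with FF. Its ethanol group holds WT_EtOH C. Leaving out the 2 libraries and WT_EtOH C, which leaves 2 against 2, Thbs1 (-5.52 ± 0.53), Tgfbr3 (-2.42) and Myl10 (-2.96) fell in WT (edgeR adjusted p = 0.0014, 0.0014 and 0.0149), and camera called 14 lists (0 with an estimated correlation). Thbs1 was then at 1100 and 1130 CPM in ethanol and at 25.7 and 22.8 CPM in 4OHT. Tgm2 was the other of the 4 genes past the threshold there, but its level was the reason for leaving WT_EtOH C out, so its value in that fit is no test. Genes named from that fit were chosen after their values were seen, and Thbs1, Tgfbr3 and Myl10 are among the 27 genes at which WT_EtOH C lay mostly with 4OHT, so their calls are not independent of leaving it out. Over all 18 libraries no list member passed in either line. Camera with the preset correlation called 13 lists in Het and 8 in WT, and with an estimated correlation 0 in each. In Het 11 of these lists were up and 2 down, which rested in part on Het_4OHT A, the library that stood apart: without it 5 were up and 5 down. The cytosolic and mitochondrial ribosomal protein lists went from up (preset adjusted p = 1.67e-05 and 3.34e-10) to down (1.8e-14 and 0.000699). In WT the snoRNA list went from down (0.032) to up (0.0488) without WT_4OHT C. The Het number was 6 without Het_EtOH B or Het_4OHT C, and the WT number was 4, 5 and 2 without WT_EtOH A, WT_EtOH B and WT_4OHT A. In Het the medians of snoRNAs (0.08) and interferon-stimulated genes (0.07) were above 0 while camera gave both as down, and in WT the MLL-AF9 list had a median of -0.11 and a mean of 0.41. Across genes, which are not independent replicates, log2 fold changes of FF and Het had Pearson r = 0.213 and Spearman rho = 0.147, FF and WT 0.185 and 0.192, and Het and WT 0.026 and 0.234. Single libraries carried these values: r for FF and WT was 0.0418 without FF_EtOH C, r for FF and Het 0.056 without Het_4OHT B, and r for Het and WT between -0.0257 without Het_4OHT B and 0.215 without WT_4OHT C.

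The FF response differed from that of WT for 296 genes, 53 with a higher and 243 with a lower log2 value, and from that of Het for 321 genes, 52 and 269. Dhx16, an RNA helicase of the spliceosome, went from 118 ± 9.32 to 37.3 ± 1.78 CPM in FF (SD, n = 3). Its difference was -1.68 from WT and -1.74 ± 0.14 from Het (edgeR adjusted p = 1.93e-05 and 1.12e-05). Snora7a, Snora70, Clec4n, Phlda3 and the snoRNA host Dancr (2.13) responded more in FF than in WT, and Scd1, Plekhh2, Bcat1, the kinase Matk (-1.84) and the phosphatase Ptpru (-1.71) were lower. Against Het, Lyz1 (7.19 ± 1.63), Ccdc107 (-1.87) and Sh2d5 (-1.77) were added. Of the calls against Het named by the rule, 10 were kept and 1 was lost with the replicate block. All 11 were kept with the block within each line. Lyz1 was at 8.93 CPM in Het_EtOH B and at most 0.194 CPM in the other 5 Het libraries, so its value rests on that library (2.75 without it, edgeR adjusted p = 0.293). Without the 2 libraries 118 genes differed from WT and 319 from Het. Clec4n, Phlda3 and Ptpru then did not differ from WT (edgeR adjusted p = 0.0986, 0.122 and 0.0574), nor Phlda3 from Het (0.0524). Without these and WT_EtOH C, 72 differed from WT, and Snora7a, Clec4n, Phlda3, Scd1, Plekhh2, Bcat1 and Ptpru did not (edgeR adjusted p 0.05 to 0.175), nor did Lyz1 differ from Het (0.0611). The WT count was 106 and 89 without WT_EtOH A and B, 110 and 134 without WT_4OHT B and C, 157 and 162 without FF_EtOH A and B, and 122, 125 and 83 without FF_4OHT A, B and C. The Het count was 178, 157 and 68 without FF_4OHT A, B and C, 91, 104 and 199 without Het_EtOH A, B and C, and 199 without Het_4OHT C. Ddx41, Bcat1, Ccdc107, Dancr, Dhx16, Matk, Snora70 and Snora7a passed against WT with any of the 12 libraries left out, and Ddx41, Bcat1, Ccdc107, Dhx16 and Snora70 against Het. Clec4n, Phlda3, Plekhh2, Ptpru and Scd1 lost the call against WT without any of 5 to 9 single libraries (edgeR adjusted p 0.0501 to 0.105). Clec4n, Phlda3, Plekhh2, Sh2d5, Snora7a and Lyz1 lost it against Het without any of 3 to 9 (0.0503 to 0.293). The snoRNA and G2/M lists differed from WT with an estimated correlation (camera adjusted p = 0.0459 and 0.0231) and from Het (0.0131 each), but not without the 2 libraries (0.117 and 0.111 against WT, 0.085 and 0.0806 against Het). Without these and WT_EtOH C the adjusted p was 0.0127 for snoRNAs and 0.127 for G2/M against WT, and 0.0654 for each against Het. Between Het and WT responses edgeR found 0 genes, with 233 at an unadjusted p of 0.05, 0 in limma voom and 4 in DESeq2. The 233 genes are also less than 0.05 of the tested genes.

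In ethanol, Het differed from WT at 3049 genes, 1714 higher and 1335 lower (2185 higher and 900 lower when scaled by library size). Eya1, a transcriptional coactivator, was at least 2880-fold higher, Pea15a at least 923-fold, the transcription factor Ikzf2 at least 902-fold, Mir682 at least 779-fold and Adm at least 695-fold, against a floor of 3 counts over the WT group. Sdk1 was lower by a ratio of 416 (95% counting interval 142 to 2020), and Ugt8a (-7.44), the adhesion molecule Vcam1 (-7.11), Fam115a (-6.81) and Cftr (-6.80) were lower too. FF against WT gave 0 genes in edgeR, with 707 at an unadjusted p of 0.05, 0 in limma voom and 27 in DESeq2. Leaving out the 2 libraries gave 614, 418 higher and 196 lower, and leaving out WT_EtOH C as well gave 479, 352 higher and 127 lower.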

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

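The tests of the libraries out of place, of the monocyte genes and of the loss of both alleles were chosen after the results were seen, and those of Rn45s, of short features and of other splits before. The response of FF cells to 4OHT differed from that of WT for 296 genes and from that of Het for 321 in edgeR. Among 112 named genes, 38 differed from WT and 6 more from Het alone, all by a test of the difference itself. Against WT the log2 differences were 3.32 for Snora7a, 2.54 for Clec4n, 3.09 for Snora70, 2.04 for Phlda3, 2.13 for Dancr, 2.98 for Snora16a, 1.90 for Snhg1, 1.495 for Snhg12, 1.12 for Gas5, 1.25 for Snhg3, 0.95 for Hoxa5, 1.93 for Lyz2 and 0.76 for Prpf3. Lower values were -2.34 for Plekhh2, -2.35 for Scd1, -2.04 for Bcat1, -1.84 for Matk, -1.71 for Ptpru, -1.69 for Ccdc107, -1.68 for Dhx16, -2.49 for Ddx41, -0.82 for Polr1a, -0.60 for Nat10, -0.93 for Shmt2, -0.91 for Phgdh and -0.86 for Sdf2l1. Cell cycle and repair genes differed by -0.97 for Rfc5, -0.86 for Pold1, -0.71 for Mcm7, -0.59 for Clspn, -0.83 for Kif20a, -0.57 for Ckap2l, -0.72 for Ccna2, -0.54 for Dlgap5, -0.75 for Rad54l and -0.78 for Fanca. Nsdhl differed by -0.88 and Tm7sf2 by -1.25. Against Het the differences were 7.19 for Lyz1, -1.77 for Sh2d5, 3.36 for Snord88c, -0.66 for Bop1, -0.87 for Herpud1 and -0.99 for Srsf6. With an estimated correlation, camera adjusted p was 0.0459 for snoRNAs and 0.0231 for G2/M genes against WT, and 0.0131 for each against Het. These were 0.117 and 0.111 against WT and 0.085 and 0.0806 against Het without the 2 libraries. Many of these differences rest on single libraries: with each of 12 libraries left out in turn, 13 of the 38 differences from WT passed every time (Snora7a, Snora70, Snhg1, Dancr, Bcat1, Matk, Ccdc107, Dhx16, Ddx41, Rfc5, Pold1, Kif20a and Nsdhl). The other 25 lost their call in 1 to 12 of these fits (edgeR adjusted p up to 0.195), among them Plekhh2 in 5, Clec4n and Scd1 in 6, Ptpru in 7, Phlda3 and Lyz2 in 9, Ccna2 in 11 and Fanca in 12. All 6 from Het alone lost it in 4 to 9. Of the 38, 22 did not pass without the 2 libraries and 28 without these and WT_EtOH C. Among the 13 listed, Snhg1 and Nsdhl did not pass without the 2 libraries (edgeR adjusted p = 0.0529 and 0.0541). Without these and WT_EtOH C, Snora7a, Bcat1 and Nsdhl did not (edgeR adjusted p = 0.0775, 0.0544 and 0.0776). Lyz1 was at 2.75 without Het_EtOH B (edgeR adjusted p = 0.293), and 72 genes differed from WT without the 2 libraries and WT_EtOH C.

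Chance is not excluded for the counts of FF minus WT and FF minus Het, since the splits cannot decide it. Of 100 splits of the libraries, 7 gave at least 296 genes for FF minus WT (highest other 994) and 7 gave at least 321 for FF minus Het (highest other 1498). For Het minus WT the real count was 0 (highest other 72), which all 100 reach by construction, so its splits decide nothing. The 7 splits in both cases kept the FF libraries parted by treatment, as 9 of 100 did. They therefore hold the FF response itself and are no measure of chance. Among the 91 others the highest counts were 13 and 0. For lists, 17 of 100 splits gave at least 16 for FF minus WT (highest other 19), 67 at least 9 for Het minus WT (17) and 14 at least 16 for FF minus Het (18). With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real count and the highest other were 1729 and 0 for FF (1 split as large), 2 and 0 for Het (1), 0 and 200 for WT (10), where the split with 200 set WT_EtOH A, WT_EtOH B and WT_4OHT A against the others and points to a structure of these libraries, 0 and 0 for FF against WT in ethanol (10) and 3049 and 0 for Het against WT in ethanol (1). A real count of 0 is reached by every split there too. For lists they were 16 and 16 in FF (3), 13 and 13 in Het (2) and 8 and 11 in WT (6).

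The library labelled FF_EtOH C lay with the WT libraries and the library labelled WT_4OHT C with the FF libraries. Of 59 genes that separate the other libraries of both lines by at least 4-fold, 100% and 98.3% lay with the other line, against at most 1.67% in any of the remaining WT and FF libraries, which argues against drift of the cultures. At genes on in 1 line alone, the highest median level was 0.388% of the labelled line's, which argues against mixed cells or RNA. At 27 genes whose treatment difference had 1 sign in all 3 lines, found without these libraries, WT_EtOH C and Tgm2, the library labelled FF_EtOH C lay on the WT 4OHT side at 3.7% (exact 95% interval 0.0937 to 19, over genes, which are not independent), which argues against an exchange of these 2 labels alone. A rotation of 3 labels may account for the pattern. The library labelled WT_EtOH C lay on that side at 88.9% (70.8 to 97.6) and the library labelled WT_4OHT C on the FF 4OHT side at 14.8%. Y-linked Eif2s3y had 2274 counts in the library labelled FF_EtOH C and 0 in each other FF library, which argues against drift there too. It had 0 counts in the library labelled WT_4OHT C and 2247 to 2779 in the other WT libraries. Beyond drift no biological explanation was tested, and no library was relabelled.

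The snoRNA counts were higher in FF_4OHT, where Rn45s was highest in B and C. With log2 Rn45s as a covariate the median stayed at 1.38, from 1.41, which argues against carryover of ribosomal RNA as the whole cause. Calls fell from 27 to 12 as the median SE rose from 0.547 to 0.63. A general gain of counts at short features stays open: 43 other genes under 200 bases, mostly microRNA genes, had a median of 0.709, just past the 0.7 set beforehand, and 10 of them passed, all higher. Loss of both alleles may also account for it, with an adjusted p of 0.0459 against WT, which is 0.117 without the 2 libraries and 0.0127 without these and WT_EtOH C, so the rise is not called biological here.

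Monocyte and macrophage genes were higher in FF_4OHT. Their median was 1.61 without the 2 libraries, which argues against those libraries as the cause. A lower share of progenitors stays open, since the mast cell and basophil list had a median of 0.693, above a bound of -0.231. That bound is wide, so the test is weak, and the code that applied it was changed after the value was seen, to follow the prediction as written. More macrophage-like cells stay open as well and were not tested, since the members of the list that rose cannot decide it.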

How the results depend on the processing

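The fits without the 2 libraries out of place, without those and Het_4OHT A, without those and WT_EtOH C, and with a replicate block within each line were chosen after the data were seen. No gene named by the rule changed sign while past the threshold in its comparison. In WT, Tgfbr3, Myl10 and Tgm2 had log2 values of 0.46, 1.43 and 0.13 over all libraries, without a call. Without the 2 libraries and WT_EtOH C they were at -2.42, -2.96 and -3.66, past the threshold. No FF list changed direction while past the threshold without any single library, the 2 or the 3. In other comparisons lists did: without Het_4OHT A the cytosolic and mitochondrial ribosomal protein lists went from up to down in Het (preset adjusted p 1.67e-05 to 1.8e-14 and 3.34e-10 to 0.000699) and in Het minus WT (0.00144 to 2.98e-10 and 7.53e-07 to 0.00171), and without WT_4OHT C the WT snoRNA list went from down (0.032) to up (0.0488). Without a count filter 172 genes differed between FF and WT responses and 213 between FF and Het, and 8 lists passed in Het and 5 in WT. With at least 5 CPM in 3 libraries, Het treatment gave 1 gene and Het against WT in ethanol 2029, where fewer genes were tested. DESeq2 gave 17 genes in Het, 4 in WT, 648 for FF minus WT, 4 for Het minus WT, 731 for FF minus Het and 27 for FF against WT in ethanol. With only the compared groups fitted, Het gave 0, FF minus WT 460, FF minus Het 57 and FF against WT in ethanol 1. The replicate block gave 0 in Het and moved no other count of genes by more than 1.5 times. Same-letter deviations from the group means correlated at 0.39, -0.023 and 0.25 for A, B and C in WT and at 0.17, 0.18 and 0.067 in FF. Those means hold the libraries out of place, so these values cannot decide whether the letters pair the WT and FF libraries. Each FF ethanol library correlated best with its own letter in 4OHT, a hint from the data and not the design, while WT_EtOH B correlated best with A. At 2-fold the counts were 524 for FF, 117 for FF minus WT, 125 for FF minus Het and 1835 for Het against WT in ethanol. At an adjusted p of 0.01 they were 684, 49, 53 and 1801, and 0 in Het. Without the 2 libraries they were 118 for FF minus WT and 614 for FF against WT in ethanol. Without 3 libraries they were 2798 for FF, 0 for Het, 537 for FF minus WT, 673 for FF minus Het and 981 for FF against WT in ethanol, with 5 lists for Het minus WT. Without the 2 libraries and WT_EtOH C they were 12 for Het, 4 for WT, 72 for FF minus WT and 479 for FF against WT in ethanol, with 14 lists for WT. An estimated correlation there gave 2 lists for FF (snoRNAs and G2/M, adjusted p 0.0366 each), 0 for Het, 0 for WT, 1 for FF minus WT, 0 for Het minus WT and 0 for FF minus Het. With the block within each line they were 2763 for FF, 1 for Het, 630 for FF minus WT and 755 for FF minus Het.

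Camera with an estimated correlation called 1 list in FF, 0 in Het, 0 in WT, 2 for FF minus WT, 0 for Het minus WT and 2 for FF minus Het. Fry called 14 in FF (7 up and 7 down), 0 in Het, 0 in WT, 6 for FF minus WT, 0 for Het minus WT and 10 for FF minus Het. Pearson r at genes with a mean log2 CPM of at least 5 was 0.124 for FF and WT and 0.297 for Het and WT. At genes past the threshold in FF it was 0.451 for FF and Het, 0.435 for FF and WT and 0.281 for Het and WT. Without the 2 libraries Het and WT had 0.217 over all genes. At genes past the threshold in FF in that fit, r was 0.64 for Het and WT, 0.422 for FF and Het and 0.373 for FF and WT. Leaving out each library in turn gave 700 to 1293 genes for FF, 0 to 1 for Het, 0 to 0 for WT, 83 to 249 for FF minus WT, 0 to 0 for Het minus WT, 68 to 479 for FF minus Het, 0 to 1 for FF against WT in ethanol and 2215 to 2569 for Het against WT in ethanol. The lists ranged from 16 to 18 for FF, 6 to 12 for Het, 2 to 12 for WT, 14 to 19 for FF minus WT, 4 to 14 for Het minus WT and 14 to 17 for FF minus Het. Among named FF results, 11 lost their call without the 2 libraries, 10 without these and WT_EtOH C, 5 with limma voom, 29 at an adjusted p of 0.01 and 48 at 2-fold. Without FF_EtOH A, B or C, 16, 15 and 16 lost it, and without FF_4OHT A, B or C, 13, 18 and 28. The causes were not tested, except that leaving libraries out leaves fewer samples. Depth limits low genes: 3 counts over a library correspond to 0.113 CPM in WT_EtOH A.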

Other observations

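Of the 1729 genes past the threshold in FF, 58.7% had the same sign of log2 fold change in Het and 60.6% in WT. The FF genes that rose had a median of 1.05 in FF, 0.11 in Het and 0.10 in WT, and those that fell had -0.66, -0.01 and -0.01. Among the 43 short features outside the snoRNA list, Mir6913 (log2 3.39, edgeR adjusted p = 0.00226) and Mir1291 (3.17, 0.00282) had the smallest adjusted p-values in FF. They were chosen after their values were seen.

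Tgm2, a transglutaminase, had a log2 value of -3.96 in FF (edgeR adjusted p = 0.0291, lost without any of 4 single libraries) and in Het (adjusted p = 1). It passed in Het (-3.99, edgeR adjusted p = 0.00173) without the 2 libraries and WT_EtOH C, which was left out for its Tgm2 level. In WT its level went against 2 labels. It was at 220 and 227 CPM in WT_EtOH A and B and at 18.01 and 17.28 CPM in WT_4OHT A and B, but at 25.4 CPM in the library labelled WT_EtOH C and at 480 CPM in the library labelled WT_4OHT C. In the library labelled FF_EtOH C it was at 401 CPM. Across genes the library labelled WT_EtOH C correlated best with WT_4OHT B (r = 0.994), and genes are not independent replicates. Tgm2 was singled out after its values were seen, and no library was relabelled.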
